A study of Mus musculus with 6 samples.

How the data were processed

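CD45+ cells sorted from subcutaneous MC38 tumours of 3 mice given PBS and 3 mice given TIM3-ProIL2V2 were profiled with 3' droplet RNA sequencing (10x Genomics, Illumina NovaSeq). The labels of all 6 samples give CD45+ cells, while the design text of the series speaks of isolated intratumoral CD8+ T cells; the labels were followed, and the sort itself was not checked against another source. Per the labels, mice received 2 intraperitoneal injections, 1 every 3 days, and all libraries belong to batch 1. The deposited files hold UMI counts per gene and barcode for 32285 genes, made by the authors with Cell Ranger 7.1.0 on mm10. Whether introns were counted and how barcodes were called as cells is not given. The labels call the 3 samples of a group biological replicates, so p-values measure the spread between mice. Equal replicate numbers in both groups were not read as pairs, since no label says so. Libraries held 196331068 to 244235494 UMIs in 7616 to 12705 barcodes. Gene coordinates and GC content, taken over the longest transcript of each gene, came from GENCODE vM21 (GRCm38).

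Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes were kept. Scrublet (in scanpy 1.11.5) scored each library, and the top 0.8% per 1000 barcodes were removed, 602, 457 and 622 barcodes in the PBS libraries and 1125, 1257 and 873 in the treated ones. The automatic threshold of Scrublet marked 1, 0, 0, 2156, 116 and 0 barcodes and was not used. Counts were scaled to 10000 per cell and logged. From 2000 variable genes, without T cell receptor, immunoglobulin, mitochondrial and ribosomal genes, 30 principal components and 15 neighbours were computed and cells were clustered with Leiden (leidenalg 0.10.2) at a resolution of 1.0, without integration. T and NK clusters were clustered again without cell cycle genes. Clusters were named from markers of 22 cell types, and clusters led by markers of unrelated types were left unnamed. The CD8 T-like class joined 3 clusters, led by effector, interferon and cell cycle genes. In the interferon cluster 82.5% of cells held Cd3e, 72.5% Cd8a and 12.5% the NK gene Ncr1, so the class may hold some NK cells. In the effector cluster these shares were 98.1%, 98.0% and 0.844%. Neutrophil-like and B-like clusters had low median UMIs but held their markers among their 10 leading genes. A second definition of CD8 cells was a gate on UMIs of CD8 genes.

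UMIs were summed per library and class, so that libraries and not cells were the replicates. Named immune classes with at least 30 cells in each of the 6 libraries were tested. Fibroblast-like cells, with at least 59 in each library, met that limit but were not tested. The Havcr2 subsets of CD8 T-like cells were not held to that limit: detected cells numbered 28 in PBS 3, and undetected cells 28, 26 and 28 in PBS 2, PBS 3 and TIM3-ProIL2V2 3. Helper CD4 T cells formed no class of their own and B-like cells had 13 cells in PBS 2, so neither was tested. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 0.05. Error values of log2 fold changes are standard errors. CD8 T-like cells were also split by whether at least 1 Havcr2 UMI was seen, and the interaction of treatment with that split was tested with library as a block. Havcr2 itself is not reported for that split, since it defines the split. Havcr2 RNA is not TIM3 protein, and its detection depends on depth.

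Sets of genes were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over lists) on voom values, again with an estimated correlation, and with fry. In all 32 gene lists were fixed, each used in the classes it applies to. Cells per class were compared with the edgeR quasi-likelihood test with kept cells as offset, over 12 classes, and with a two-sided exact permutation test (20 assignments, smallest p 0.1). Shares of cells with a UMI were computed as the mean share over all ways of each cell to 2000 UMIs.

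The tests, gene lists, markers, filters, most alternatives and the rule for named genes were chosen before the data were examined. By that rule the text may name genes with an adjusted p below 0.05, a mean of at least 20 CPM and no overlap between the groups, up to 10 higher and 10 lower by fold change in CD8 T-like cells and up to 5 and 5 elsewhere (for the interaction without the overlap condition). T cell receptor and immunoglobulin segments, unnamed gene models, mitochondrial and ribosomal genes and markers that define a class are not ranked. Up to 4 members of each list with the smallest p in a comparison may be named too, and in CD8 T-like cells Havcr2, Il2, Il2ra, Il2rb, Il2rg, Tcf7, Pdcd1, Ifng, Gzmb, Mki67 and Cd8a whatever their p. Taf10, Hras, Bri3 and Scand1 were named after their values were seen.

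Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, leaving out each library, the replicate number as a block, other mitochondrial limits (5% and 20%), no Scrublet removal, a resolution of 2.0, other CD8 and Havcr2 definitions, T and NK cells outside the mixed clusters as denominator of class shares, TMM scaling over classes and thinned counts, among them equal summed UMIs of the Havcr2 subsets for undetected cells. The gate outside mixed clusters, TIM3-ProIL2V2 3 alone against PBS, equal summed UMIs for detected cells and the interaction, class shares without low-Ptprc and fibroblast-like cells and class shares with CD8 cells counted by the gate were added after the data were seen.

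Of the 10 genes whose share of cells was tested, 1 that reached the smallest p is counted but not reported here by name. The pipeline was tested on simulated data with the real library sizes and 200 changed genes. At 2-fold changes it recovered 60% of genes in CD8 T-like cells, 60% in Havcr2-detected, 47% in Havcr2-undetected, 51% in regulatory T-like, 66% in NK-like, 59% in monocyte or macrophage-like, 71% in dendritic-like and 21% in neutrophil-like cells and 33% in the interaction. At 4-fold changes the same order gave 90%, 92%, 85%, 87%, 90%, 91%, 96%, 79% and 82%. False calls numbered 13, 11, 10, 5, 6, 13, 25, 6 and 15, and with no gene changed 2, 0, 0, 0, 1, 0, 0, 0 and 1. Without the filter on low counts, unchanged data gave 27 calls in monocyte or macrophage-like, 9 in dendritic-like and 0 to 2 in the other cells. Camera called 2 of 2 shifted lists and 0 of 18 others. Genes were drawn independently there, so this cannot show false calls that come from correlated genes. On the real CD8 T-like sums the splits of libraries other than the real one called 1 to 13 lists. The test of class shares called a 4-fold change in 28% and a 16-fold change in 68% of 100 draws, with 8 calls over all draws of 12 unchanged classes. Smaller changes than these can be missed at this depth. Correlations between same-numbered libraries were -0.14, -0.051 and -0.025 in CD8 T-like cells. Libraries of the same group were checked for duplicates in CD8 T-like, monocyte or macrophage-like and NK-like cells, and the lowest chi-square per gene between a pair was 2.01. PBS libraries were not compared with treated ones in this check.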

Results

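By their labels, single-cell RNA libraries were made from CD45+ cells sorted from subcutaneous MC38 tumours, which grow from a mouse colon carcinoma line. Tumours came from 3 mice injected with PBS and 3 mice injected with TIM3-ProIL2V2, and each mouse gave 1 library. By its title the series concerns an IL2 that is activated in the tumour and aimed at TIM3+ CD8 T cells. TIM3 is the protein encoded by Havcr2, an inhibitory receptor of T cells that myeloid cells also carry. The PBS libraries held 196331068, 198178554 and 216640052 UMIs (unique molecular identifiers, which count RNA molecules). The TIM3-ProIL2V2 libraries held 197830313, 244235494 and 229335941. After filtering, 7976, 7038 and 8085 cells were kept in PBS 1, 2 and 3, and 10598, 11107 and 9456 in TIM3-ProIL2V2 1, 2 and 3. Median UMIs per barcode were 18219, 21251 and 19732 in the PBS libraries and 12858, 16701 and 19062 in the treated ones.

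Monocyte or macrophage-like cells made up 52.6%, 65.8% and 62.6% of kept cells in the PBS libraries and 48.1%, 71.6% and 73.0% in the treated libraries. CD8 T-like cells, the class the study's design text asks about, made up 1.40%, 0.867% and 0.668% of cells in PBS 1, 2 and 3 and 11.4%, 1.81% and 0.687% in TIM3-ProIL2V2 1, 2 and 3. Their mean share was 0.980% ± 0.381 (SD, n = 3) against 4.64% ± 5.89 (SD, n = 3), and the highest value was that of a single treated mouse. Within T and NK cells, CD8 T-like cells held 19.3%, 18.2% and 17.6% in the PBS libraries and 49.0%, 33.3% and 24.3% in the treated ones. This leaves out barcodes that carried T or NK genes together with macrophage genes. Such mixed barcodes were 60.0%, 66.4% and 72.1% of all T and NK barcodes, mixed ones included, in PBS and 19.2%, 39.5% and 53.6% in treated libraries. The difference therefore depends on leaving them out. NK-like cells, innate killer lymphocytes, held 3.10%, 2.32% and 1.67% against 6.48%, 1.90% and 0.909%. Dendritic-like cells, which present antigen to T cells, held 4.45%, 4.65% and 4.82% against 3.84%, 2.30% and 2.13% (log2 fold change -0.75 ± 0.37 SE, and -0.35 with TMM scaling over classes). Plasmacytoid dendritic-like cells held 0.301%, 0.256% and 0.334% against 0.208%, 0.162% and 0.137%.

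The edgeR test on cell numbers called 0 of 12 classes at an adjusted p of 0.05, with 1 class (B-like) at an unadjusted p below 0.05. CD8 T-like cells had a log2 fold change of 2.24 ± 1.04 (SE; adjusted p = 0.251; exact permutation p = 0.3, two-sided), and B-like cells one of -4.33 ± 1.28 (adjusted p = 0.156; exact permutation p = 0.4). The CD8 value was 0.35 without TIM3-ProIL2V2 1 and 0.35 with CD8 cells counted by a gate on UMIs. It was 0.96 within T and NK cells, mixed barcodes left out, 1.37 with the replicate number as a block and 2.45 with TMM scaling over classes. B-like cells held 10.1%, 0.185% and 3.02% of the PBS libraries and 0.226%, 0.198% and 0.233% of the treated ones. The exact permutation p of dendritic-like and plasmacytoid dendritic-like cells was 0.1, the smallest that 3 against 3 mice can give. With TMM scaling over classes their log2 fold changes were -0.35 and -0.39, and that of monocyte or macrophage-like cells 0.63. No class passed there (lowest adjusted p = 0.0812, edgeR). Unadjusted p-values were 0.0183 for CD8 T-like, 0.0271 for regulatory T-like, 0.0218 for neutrophil-like and 0.00992 for B-like cells. Without PBS 1 the B-like log2 fold change was -2.86. Without PBS 2 the B-like share passed the edgeR threshold, and without TIM3-ProIL2V2 1 the dendritic-like share did, 1 class in each case.

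**Figure D1:**
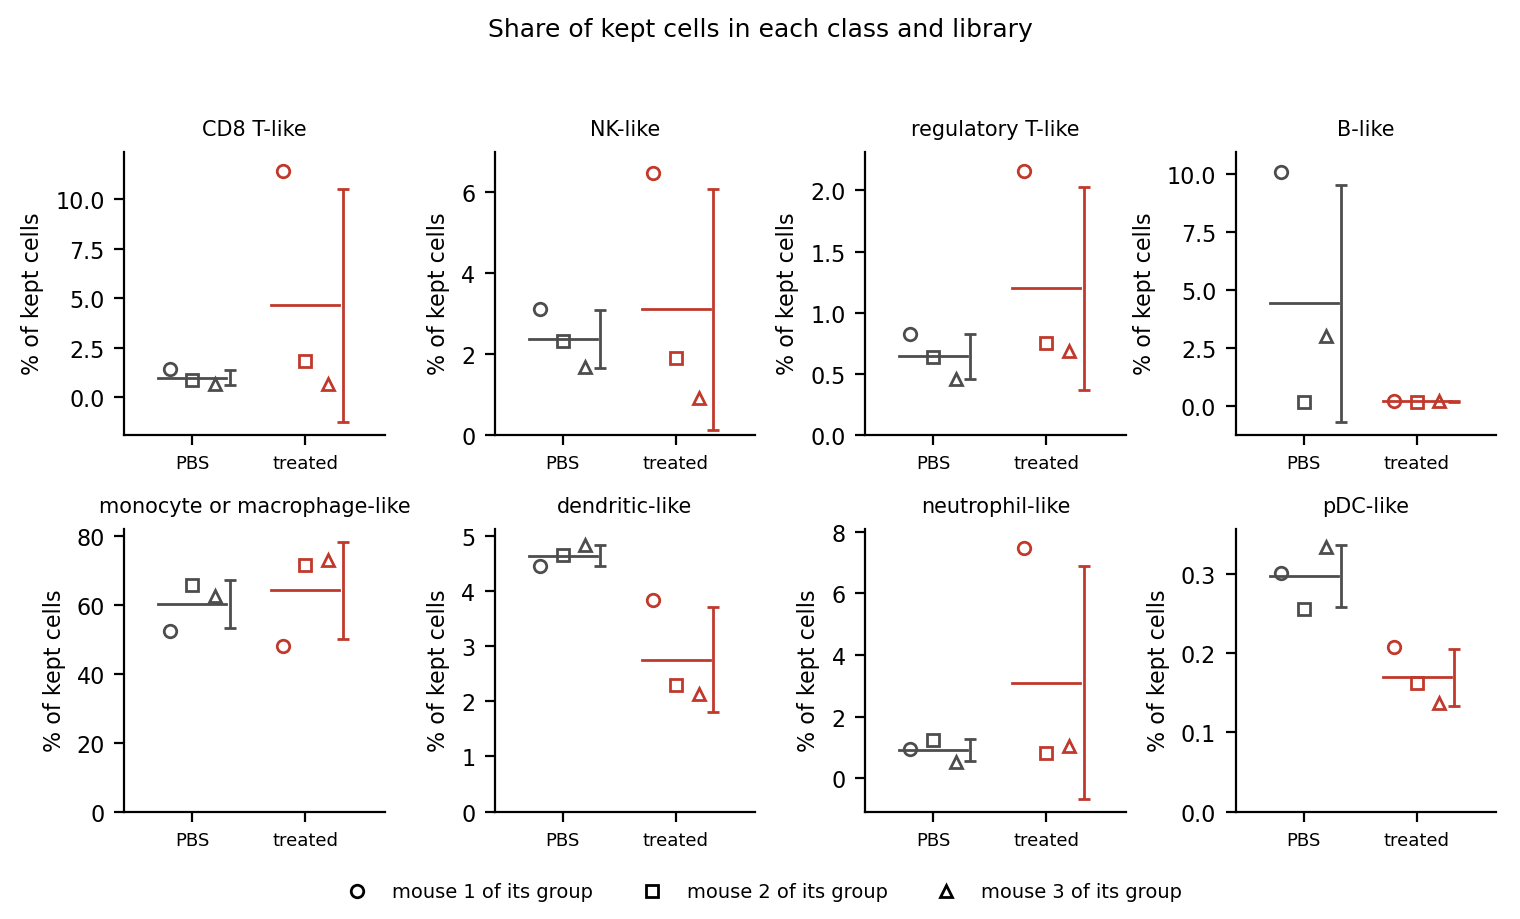
Share of kept cells (%, linear axes that include 0) of 8 cell classes in each of the 3 PBS and 3 TIM3-ProIL2V2 (treated) libraries; open symbols are mice, horizontal lines are group means and error bars are 1 SD. The CD8 T-like share of TIM3-ProIL2V2 1, 11.4%, stands above all others, which lie between 0.668% and 1.81%.

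Many barcodes carried T or NK genes together with macrophage genes, and their clusters were left unnamed. They held 10.9%, 9.43% and 9.80% of kept cells in the PBS libraries and 5.52%, 3.56% and 3.28% in the treated ones, a mean of 10.0% ± 0.768 against 4.12% ± 1.22 (SD, n = 3; exact permutation p = 0.1). That all treated libraries lay below all PBS libraries depends on the removal of doublets: without it the shares were 11.5% ± 0.872 against 7.48% ± 3.67 (SD, n = 3; exact permutation p = 0.3), and TIM3-ProIL2V2 1, at 11.6%, lay among the PBS libraries. A gate on UMIs of CD8 genes alone took 7.35%, 4.40% and 4.81% of cells in the PBS libraries and 15.3%, 3.98% and 1.87% in the treated ones, against the CD8 T-like class shares above. Of the gated cells, 74.1%, 78.7% and 81.7% lay in the mixed clusters in the PBS libraries and 18.3%, 45.7% and 58.8% in the treated ones. The CD8 T-like class therefore leaves out most gated CD8 barcodes of PBS tumours.

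The comparison of CD8 T-like cells asks how gene expression in intratumoral CD8 T cells differed after the treatment. It used sums over 112, 61 and 54 cells of the PBS libraries (1229952, 709203 and 495132 UMIs) and 1209, 201 and 65 cells of the treated ones (17994396, 2139741 and 775186 UMIs). Genes for granzymes, the serine proteases of killer cell granules, were among those that rose most. Gzmg (ENSMUSG00000040284; GRCm38 chromosome 14, 56156582 to 56159579) rose from 3.41 ± 3.10 to 80.9 ± 18.3 CPM (UMI counts scaled to library size; mean ± SD, n = 3 mice per group), a log2 fold change of 4.64 ± 0.42 (SE; adjusted p = 0.000657). Gzmf (ENSMUSG00000015441; chromosome 14, 56205263 to 56211417) rose from 551 ± 282 to 3377 ± 1306 CPM (log2 2.60 ± 0.39, adjusted p = 0.0190). Gzmc (ENSMUSG00000079186; chromosome 14, 56231441 to 56234656) rose from 356 ± 150.0 to 1801 ± 622 CPM (log2 2.34 ± 0.29, adjusted p = 0.00748). Ccl1 (ENSMUSG00000020702; chromosome 11, 82176657 to 82305690), a chemokine that binds Ccr8, fell from 716 ± 99.4 to 99.3 ± 20.6 CPM (log2 -2.83 ± 0.17, adjusted p = 3.6e-05). Ccr7 (ENSMUSG00000037944; chromosome 11, 99144196 to 99155077), the receptor that guides T and dendritic cells to lymph nodes, fell from 67.8 ± 29.4 to 11.4 ± 3.07 CPM (log2 -2.68 ± 0.31, adjusted p = 0.00505). Cxcl10 (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, fell from 130 ± 40 to 20.2 ± 2.10 CPM (log2 -2.61 ± 0.23, adjusted p = 0.000657). In each of these genes all 3 treated libraries lay on the same side of all 3 PBS libraries. That order was a condition for naming a gene, so it adds no support, and chance gives it in 10% of genes. The class holds finer clusters whose mix differed, looked at after the data were seen. A cluster led by Gzmf and other granzyme genes held 4.36% ± 0.614 (SD, n = 3) of CD8 T-like cells in PBS and 19.7% ± 9.70 in treated libraries, and a cluster led by Ccl4 and Ccl1 held 10.7%, 8.20% and 11.1% against 0.993%, 0.995% and 4.62% (exact permutation p = 0.1 for both). The first held 5, 3 and 2 cells in PBS and 363, 37 and 7 in treated libraries, the second 12, 5 and 6 against 12, 2 and 3. With so few cells these shares are less certain than the SD of the PBS libraries shows. These clusters were drawn from the same genes, so a change in the mix of cells and a change within cells were not separated.

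Other genes that rose were Gstm5, a glutathione transferase (log2 2.23), Mt2, a metal-binding metallothionein (log2 1.94), the interferon-inducible membrane protein genes Ifitm1 (log2 1.35) and Ifitm2 (log2 1.28), and Ctla2b, a cysteine protease inhibitor (log2 0.97). Ctla2b went from 84.3 ± 1.95 to 167 ± 5.20 CPM (adjusted p = 0.00855). Bach2, a transcription factor that restrains effector differentiation, fell from 193 ± 4.43 to 87.8 ± 20.7 CPM (log2 -1.10 ± 0.16, adjusted p = 0.0190). Ccnd2, which encodes cyclin D2, fell from 196 ± 7.75 to 100.1 ± 9.65 CPM (log2 -0.98, adjusted p = 0.00867). Etv6 (log2 -0.93), Kdm2b (log2 -0.92) and the nuclear long non-coding RNA Malat1 (log2 -0.60) fell as well. Klra4, an NK receptor gene of the Ly49 family, fell from 31.4 ± 21.6 to 0.725 ± 0.871 CPM. Low-Ptprc cells, which lack most RNA of the gene for CD45, held Klra4 RNA at a mean of 187 CPM. Bach2 and Malat1 were also lower in treated than in PBS libraries, without overlap, in low-Ptprc cells. The Gzm, Ifitm and Klra families hold paralogs of similar sequence, so the assignment of UMIs among their members is uncertain.

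**Figure D2:**
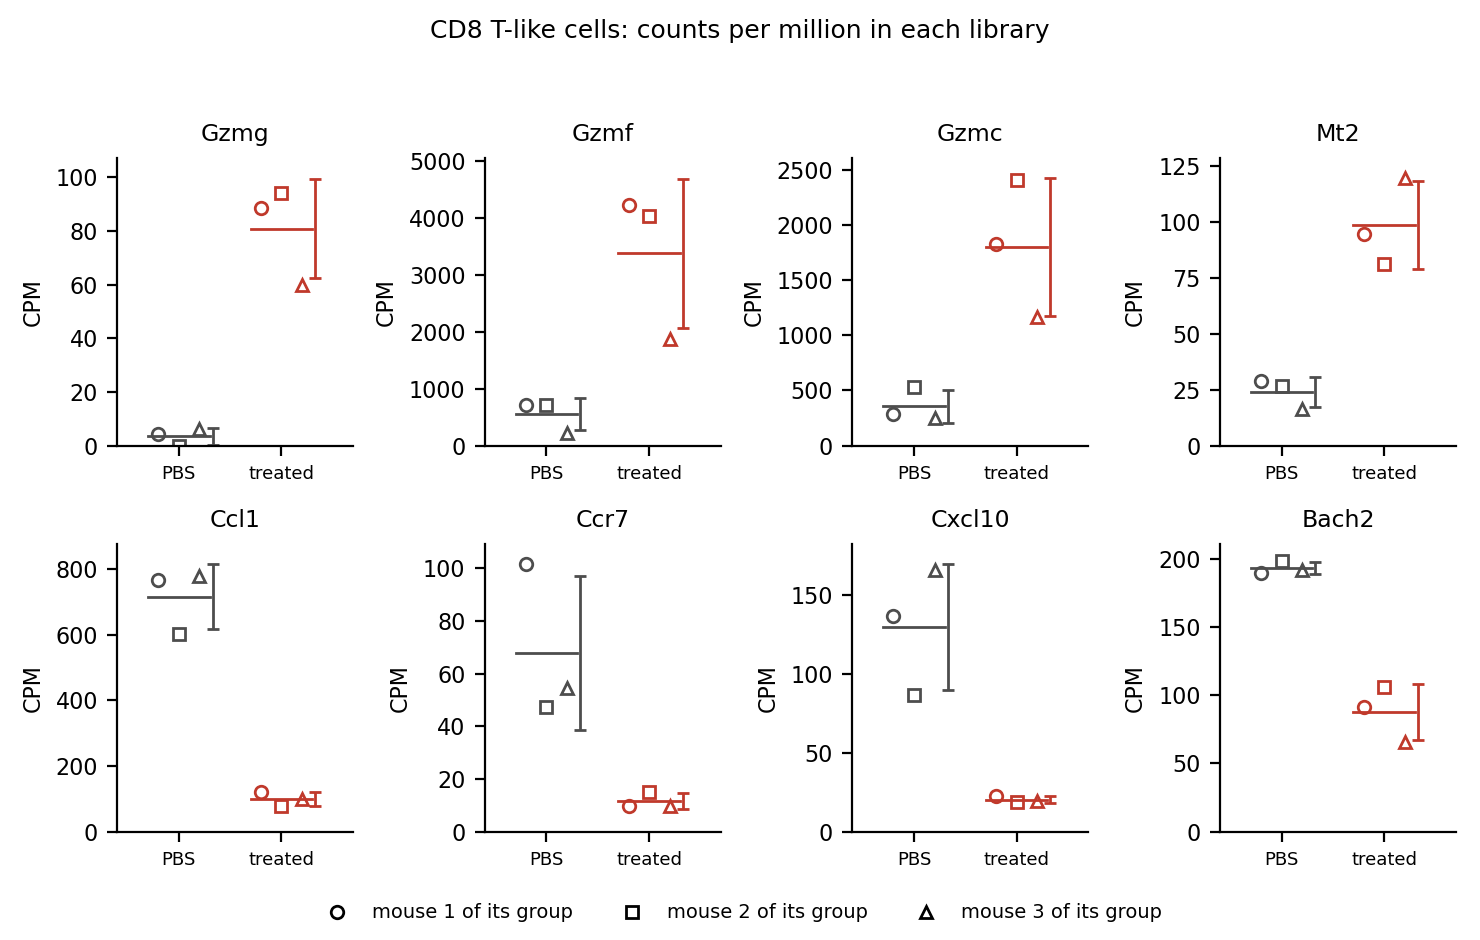
CPM, UMI counts scaled to library size (linear axes from 0) of 8 genes in CD8 T-like cells of each PBS and TIM3-ProIL2V2 (treated) library; open symbols are mice, horizontal lines are group means and error bars are 1 SD. For Gzmg the treated libraries lie at 88.4, 94.3 and 60.0 CPM and the PBS libraries at or below 6.06 CPM.

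By the edgeR test 21 of 7680 genes passed, 9 higher and 12 lower in treated tumours, with 956 genes at an unadjusted p below 0.05. DESeq2 called 74. Gzmf, Ifitm1, Pdcd1 and Cd8a are among the 10 leading genes of the main CD8 T-like cluster, so their values depend on where that cluster ends. In gated CD8 cells outside the mixed clusters, an alternative chosen after the data were seen, the log2 fold changes were 2.63 for Gzmf, 1.32 for Ifitm1, 0.30 for Pdcd1 and -0.26 for Cd8a. There Cxcl10 no longer passed (log2 -0.87, adjusted p = 0.294; 1.0e-34 to 0.294 over its alternatives), nor did Ccnd2 (0.120), Etv6 or Kdm2b (0.0532 for both). Gzmg, Mt2, Ccl1, Ccr7 and Cxcl10 passed whichever library was left out. Gzmf did not pass without PBS 1 (adjusted p = 0.108), PBS 2 (0.0882) or TIM3-ProIL2V2 2 (0.0543), nor Gzmc without PBS 1 (0.101) or PBS 3 (0.0589), nor Ifitm1 without PBS 1 (0.0957), PBS 2 (0.154), PBS 3 (0.234) or TIM3-ProIL2V2 2 (0.10). Gstm5, Ctla2b, Bach2, Ccnd2, Etv6, Kdm2b and Malat1 did not pass without PBS 1 (0.0765 to 0.213), PBS 2 (0.0771 to 0.149) or PBS 3 (0.0624 to 0.268), and Ccnd2, Etv6, Kdm2b and Malat1 not without TIM3-ProIL2V2 2 either (0.0543 to 0.125). After a GC correction Malat1 did not pass (log2 -0.53 ± 0.099, adjusted p = 0.0614). Etv6 also failed without TIM3-ProIL2V2 1 (0.0636), Ifitm2 without PBS 1 (0.0667) and Klra4 without PBS 2 (0.0882), PBS 3 (0.0624) or TIM3-ProIL2V2 2 (0.0543). With the gate that includes mixed clusters Gzmg, Mt2, Ccl1 and Ccr7 did not pass (0.114, 0.0856, 0.0528 and 0.140), nor did Bach2, Ccnd2, Malat1 and Kdm2b (0.0612, 0.107, 0.0672 and 0.979, with Kdm2b at log2 -0.0078). Leaving out PBS 1, PBS 2, PBS 3 or TIM3-ProIL2V2 2 gave 8, 7, 8 and 11 genes, and leaving out TIM3-ProIL2V2 3 gave 228. TIM3-ProIL2V2 3 alone against the PBS libraries gave 49, with a single library in 1 arm.

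Havcr2 and the genes of the IL-2 receptor chains did not pass in CD8 T-like cells. Havcr2 was at 123 ± 22.8 CPM in PBS and 184 ± 47.9 CPM in treated libraries (log2 0.61 ± 0.20, adjusted p = 0.245). The genes of the IL-2 receptor chains had log2 fold changes of 0.11 ± 0.20 (Il2ra), 0.20 ± 0.12 (Il2rb) and -0.37 ± 0.12 (Il2rg). Pdcd1, which encodes PD-1, was at 427 ± 10.5 and 500.4 ± 40.9 CPM (log2 0.22 ± 0.11, adjusted p = 0.437). Values for Gzmb were 548, 984 and 382 CPM in PBS and 2712, 2083 and 814 CPM in treated libraries (log2 1.55 ± 0.40, adjusted p = 0.151). Ifng, the gene of interferon-gamma, had a log2 fold change of -0.14 ± 0.30, the proliferation gene Mki67 one of 0.09 ± 0.25 and Cd8a one of -0.32 ± 0.12. Il2 and the memory transcription factor gene Tcf7 had too few UMIs to be tested: Tcf7 had 15, 7 and 8 UMIs in the PBS libraries and 62, 8 and 3 in the treated ones. For Il2 the numbers were 168, 2 and 1 against 36, 3 and 1.

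Among the fixed gene lists, the cytotoxic effector list was higher in treated CD8 T-like cells by camera (adjusted p = 1.9e-05; 0.269 with an estimated correlation, which ends the call; median log2 0.46). Of its 18 measured members 3 rose, 0 fell and 15 did not pass, and adjusted over the list alone 7 were higher. Gzmg, Gzmf and Gzmc passed, and Gzma went from 188 ± 73.4 to 1295 ± 972 CPM without passing (adjusted p = 0.111). The stem-like and memory list was lower (adjusted p = 0.00472; 0.269 with an estimated correlation; median log2 -0.35), with Ccr7 and Bach2 fallen among 10 measured members and 3 lower when adjusted over the list alone. Xcl1, a chemokine of this and the cytokine list, had a log2 fold change of -1.26 ± 0.30 (adjusted p = 0.132). The cytokine and chemokine list was lower (adjusted p = 7.0e-05; 0.269 with an estimated correlation; median log2 -0.36): 12 of 13 members had negative values, 1 fell (Ccl1), and adjusted over the list alone 5 were lower, with Ccl4 at log2 -0.84 ± 0.18 (adjusted p = 0.0896). The KLRG1-type effector list (adjusted p = 0.0119; 0.324 with an estimated correlation; Zeb2 log2 -0.91, 0 of 9 called, 3 lower adjusted over the list alone) and the costimulatory receptor list (adjusted p = 0.0214; 0.269 with an estimated correlation; 0 of 8 called, 3 lower adjusted over the list alone) were lower too. In gated cells outside the mixed clusters the KLRG1-type list did not pass (adjusted p = 0.118). Without PBS 1 or TIM3-ProIL2V2 2 the costimulatory list had an adjusted p of 0.165 or 0.0521 (its alternatives ran from 0.00434 to 0.269).

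Lists of energy metabolism were higher in treated CD8 T-like cells, with no single member past the threshold, and no list passed with an estimated correlation. The oxidative phosphorylation list (adjusted p = 2.5e-08; 0.324 with an estimated correlation; median log2 0.19) had 34 of 35 members above 0, and Cox5b, a subunit of cytochrome c oxidase, was at log2 0.40 ± 0.11. Adjusted over the list alone 0 members passed. The glycolysis list (adjusted p = 0.000491; 0.351 with an estimated correlation; median log2 0.37; Gapdh log2 0.42 ± 0.12) had 2 higher members and the hypoxia list (adjusted p = 0.00104; 0.269 with an estimated correlation; median log2 0.40; Bnip3 log2 1.48 ± 0.30) had 4, adjusted over the list alone. The type I interferon response list was lower (adjusted p = 5.0e-05; 0.351 with an estimated correlation; median log2 -0.76): 16 of 17 members had negative values, 0 passed, and adjusted over the list alone 7 were lower, with Ifit3 at log2 -1.79 and Isg15 at log2 -1.21. A cluster led by interferon genes held 5.36%, 11.5% and 5.56% of CD8 T-like cells in PBS (6, 7 and 3 cells) and 5.05%, 0.995% and 1.54% in treated libraries (61, 2 and 1 cells). Of its cells 12.5% held the NK gene Ncr1, and how far it bears on the interferon list, the NK list or Klra4 was not tested. In gated cells outside the mixed clusters the interferon list no longer passed and changed sign (adjusted p = 0.904; 8.9e-11 to 0.904 over its alternatives).

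Lists for the IL-2 and STAT5 response (25 measured, 0 higher and 1 lower called, Ccnd2, with 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.337) and for inhibitory receptors and exhaustion (17 measured, 0 called, 0 adjusted over the list alone, adjusted p = 0.180) did not pass. Among the former, Socs2, a feedback inhibitor of cytokine signalling, was at log2 1.24 (adjusted p = 0.160). The migration list had a test direction of down with a median of 0.0095. Of the marker lists of other cell types, that of macrophages did not pass (adjusted p = 0.371; median log2 -0.17; Lyz2 log2 -0.75, adjusted p = 0.356; list adjusted p = 0.00331 without TIM3-ProIL2V2 2, with 0.00331 to 0.921 over its alternatives) and that of NK cells was lower (adjusted p = 0.00521, 0 of 3 members above 0, 1 called, 2 lower adjusted over the list alone; adjusted p = 0.269 with an estimated correlation and 0.284 in gated cells outside the mixed clusters). Ighm, an immunoglobulin gene of B cells, and Cd83, which dendritic and B cells express, were among the 12 lower genes and are named after their values were seen. In all, camera called 15 of 22 lists with the preset correlation and 0 with an estimated one. The fry test, which asks whether the genes of a list move one way on balance, also called 0.

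The share of CD8 T-like cells with a UMI was compared after each cell had been thinned to 2000 UMIs. Tcf7 was seen in 2.79%, 3.08% and 2.94% of cells in the PBS libraries and 0.789%, 1.01% and 0.437% in the treated ones (exact permutation p = 0.1, the smallest possible). Its share in neutrophil-like cells, which should lack it, was at most 0.842%, so the treated values are at or near background. For Pdcd1 the shares were 51.9%, 49.5% and 55.0% against 58.0%, 59.7% and 62.1% (exact permutation p = 0.1; at most 0.977% in neutrophil-like cells). Slamf6, a receptor of memory-like T cells, was seen in 3.23%, 1.38% and 2.27% against 0.854%, 1.20% and 0.379% (exact permutation p = 0.1). Neutrophil-like cells gave up to 2.50% for Slamf6, so those shares cannot be set apart from background. Lag3, an inhibitory receptor gene, was seen in 25.2%, 25.4% and 30.5% against 23.2%, 22.4% and 22.3% (exact permutation p = 0.1; at most 0.581% in neutrophil-like cells). With the gate on UMIs Lag3 went the other way, with 10.7%, 11.2% and 9.60% against 19.3%, 13.85% and 11.7% (exact permutation p = 0.1), so its direction depends on how CD8 cells were drawn. Havcr2 was seen in 17.5%, 22.5% and 19.9% against 33.0%, 22.1% and 21.8% (exact permutation p = 0.3) and Gzmb in 24.5%, 47.7% and 30.9% against 71.7%, 46.8% and 38.4% (exact permutation p = 0.3). In neutrophil-like cells the highest shares were 18% for Havcr2, whose RNA those cells hold at 108 CPM, and 3.67% for Gzmb. Thus 5 of 10 genes tested reached the smallest p that an exact permutation test of 3 against 3 mice allows, which lies above 0.05. Median depths before thinning were 8218 to 11553 UMIs in CD8 T-like and 2763 to 3575 UMIs in neutrophil-like cells.

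Havcr2 RNA, which encodes the receptor named in the treatment, was found in T cells and in myeloid cells alike. In PBS tumours it was at 165 ± 48.4 CPM (SD, n = 3) in regulatory T-like cells, 123 ± 24.4 in CD8 T-like, 112 ± 11.4 in dendritic-like, 109 ± 5.28 in monocyte or macrophage-like and 108 ± 7.07 in neutrophil-like cells, in plain CPM without TMM scaling. NK-like cells had 19.5 ± 6.78 CPM, and the low-Ptprc cells had 3.92 ± 0.458. Treated tumours had 179 ± 50 CPM in CD8 T-like, 87.5 ± 28.8 in regulatory T-like (exact permutation p = 0.2 for both), 110 ± 13.1 in monocyte or macrophage-like (exact permutation p = 0.9) and 8.68 ± 4.21 in NK-like cells (exact permutation p = 0.1). Monocyte or macrophage-like cells are the most numerous of these classes.

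The series title sets TIM3-positive beside TIM3-negative CD8 T cells, so CD8 T-like cells with and without a Havcr2 UMI were compared separately. A UMI was seen in 44.6%, 54.1% and 51.9% of CD8 T-like cells in PBS and 77.8%, 54.7% and 56.9% in treated libraries, and detected cells were deeper (medians of 8486 to 13230 UMIs against 6969 to 9141). In all T and NK cells outside the mixed clusters, macrophage markers held a median of 0.294%, 0.382% and 0.416% of UMIs in PBS libraries. In treated libraries they held 0.147%, 0.238% and 0.184%. Monocyte or macrophage-like cells hold Havcr2 RNA too, and how far macrophage RNA bears on this split and its genes was not tested. In Havcr2-detected cells Gzmg (log2 4.84 ± 0.46, adjusted p = 0.00142), Gzmf (log2 2.81 ± 0.34, adjusted p = 0.0088), Mt2 (log2 1.88) and Ifitm1 (log2 1.56) rose. Gzma, the granzyme A gene, rose from 141 ± 64.5 to 1529 ± 1103 CPM (log2 3.54 ± 0.63, adjusted p = 0.0425), with TIM3-ProIL2V2 3 at 267 CPM against 2310 and 2010. Ccl4, a chemokine gene, fell from 4337 ± 1256 to 1625 ± 340.0 CPM (log2 -1.41 ± 0.19, adjusted p = 0.0088). From the KLRG1-type effector list Cx3cr1, the fractalkine receptor gene (log2 -1.27 ± 0.22), fell, as did the transcription factor gene Zeb2 (log2 -1.12 ± 0.20, adjusted p = 0.0498), beside Ccr7 (log2 -2.20) and Chn2 (log2 -1.43). The edgeR test called 17 of 5948 genes, 9 higher and 8 lower. Left out in turn, PBS 1, PBS 2, PBS 3, TIM3-ProIL2V2 2 and TIM3-ProIL2V2 3 gave 0, 5, 9, 8 and 186 genes. Gzma, Ccr7, Chn2 and Zeb2 did not pass without any 1 of PBS 1, PBS 2, PBS 3, TIM3-ProIL2V2 1 or TIM3-ProIL2V2 2 (adjusted p of 0.0519 to 0.258), nor did Ifitm1 without PBS 2, PBS 3 or TIM3-ProIL2V2 2 (0.0595 to 0.179) or Cx3cr1 without PBS 2, PBS 3 or TIM3-ProIL2V2 1 (0.106 to 0.179). In gated cells outside the mixed clusters Gzma (0.0857) and Cx3cr1 (0.0643) did not pass. With all 6 libraries 782 genes had an unadjusted p below 0.05 and DESeq2 called 50.

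In Havcr2-detected cells the cytokine and chemokine list was lower (camera adjusted p = 1.2e-05; adjusted p = 0.170 with an estimated correlation), with 0 of 10 members above 0, Ccl4 fallen and 5 lower adjusted over the list alone. The KLRG1-type effector list was lower (adjusted p = 0.00165; 0.279 with an estimated correlation), 2 of 9 members having fallen (Cx3cr1 and Zeb2) and 3 being lower adjusted over the list alone. The cytotoxic effector list was higher (adjusted p = 0.00165; 0.279 with an estimated correlation), 3 of 18 members having risen (Gzmg, Gzma and Gzmf) and 6 being higher adjusted over the list alone. In cells with no Havcr2 UMI 3 of 5368 genes passed. Cxcl10 fell from 256 ± 72.4 to 43.1 ± 9.08 CPM (log2 -2.48 ± 0.25, adjusted p = 0.00107) and Ccr7 fell (log2 -2.30 ± 0.36, adjusted p = 0.0438). Ccl3, a chemokine gene, rose from 51.6 ± 21.5 to 258 ± 104 CPM (log2 2.14 ± 0.33, adjusted p = 0.0438). DESeq2 called 22 genes and 443 had an unadjusted p below 0.05. In gated cells outside the mixed clusters Cxcl10 did not pass there either (log2 -0.34, adjusted p = 0.871; 1.7e-21 to 0.871 over its alternatives). Ccl3 did not pass without PBS 1 (0.0878), PBS 2 (0.125) or PBS 3 (0.199), nor Ccr7 without PBS 1 (0.241), PBS 3 (0.0867), TIM3-ProIL2V2 1 (0.117) or TIM3-ProIL2V2 2 (0.0657). Leaving out PBS 3, TIM3-ProIL2V2 1 or TIM3-ProIL2V2 3 gave 1, 5 or 103 genes.

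The interaction test asked in which genes the treatment effect differed between cells with and without a Havcr2 UMI, and 7 of 7176 genes passed. Chemokine genes moved apart: Ccl3 was at 739, 302 and 447 CPM (PBS) and 370.0, 273 and 353 CPM (treated) in detected cells, but at 69.9, 27.5 and 55.0 CPM (PBS) and 195, 192 and 372 CPM (treated) in undetected cells (difference of log2 fold changes -2.78 ± 0.26, adjusted p = 2.4e-06). For Ccl4 the difference was -2.18 ± 0.27 (adjusted p = 9.3e-05). The log2 fold changes of Gzma and Gzmf were higher in detected cells (differences 2.63 ± 0.34 and 1.40 ± 0.23), and those of Chn2 (-1.70 ± 0.29) and Cx3cr1 (-1.30 ± 0.23) lower. Without PBS 1 the differences of Gzmf and Chn2 had an adjusted p of 0.225, and that of Cx3cr1 one of 0.210. Chn2 also failed without PBS 3 (0.0659) and Cx3cr1 without PBS 2 (0.0719), TIM3-ProIL2V2 1 (0.108) or TIM3-ProIL2V2 2 (0.101). Csf2, the gene of the cytokine GM-CSF, had a difference of 5.51 ± 0.63 that rested on PBS 1 and TIM3-ProIL2V2 1: without either its adjusted p was 0.272 or 0.812 (2.4e-29 to 1.00 over its alternatives). DESeq2 called 2 genes, Ccl3 and Gzma, and the Gzma difference turned to -0.59 in gated cells outside the mixed clusters. Leaving out PBS 1, PBS 2 and TIM3-ProIL2V2 3 gave 3, 13 and 14 genes.

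**Figure D3:**
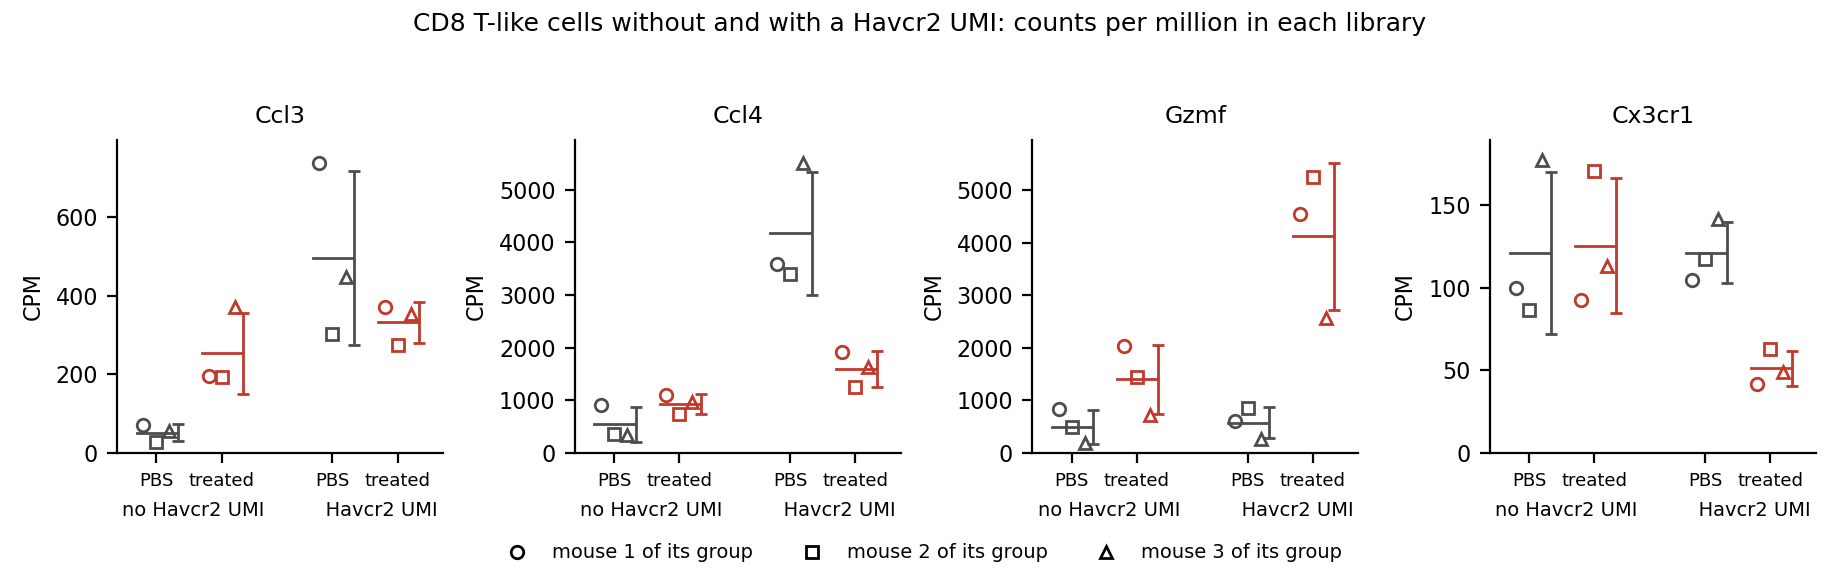
CPM, UMI counts scaled to library size (linear axes from 0) of 4 genes in CD8 T-like cells without (left pair) and with (right pair) a Havcr2 UMI, in each PBS and TIM3-ProIL2V2 (treated) library; open symbols are mice, horizontal lines are group means and error bars are 1 SD. For Ccl3 the treated libraries lie at 195, 192 and 372 CPM in cells without a Havcr2 UMI, above the PBS libraries at 69.9, 27.5 and 55.0 CPM.

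In NK-like cells the chemokine gene Ccl5 (ENSMUSG00000035042; chromosome 11, 83525778 to 83530518) rose from 3046 ± 108 to 6278 ± 991 CPM (SD, n = 3; log2 1.04 ± 0.13, adjusted p = 0.0415). It was the 1 gene of 8872 that passed by edgeR, with 888 at an unadjusted p below 0.05 and 26 by DESeq2. Without PBS 1, PBS 2, PBS 3 or TIM3-ProIL2V2 2 its adjusted p was 0.157, 0.315, 0.268 or 0.380 (1.3e-19 to 0.380 over its alternatives), and after a GC correction it was 0.0537. Without TIM3-ProIL2V2 3, 293 genes passed, 2 without PBS 1, 1 without TIM3-ProIL2V2 1 and 0 without PBS 2, PBS 3 or TIM3-ProIL2V2 2. Granzymes went opposite ways without passing: Gzma was at log2 0.70 ± 0.15 (adjusted p = 0.116), Gzmg at -1.96 ± 0.49 (adjusted p = 0.142) and Gzme at -1.18 ± 0.33 (adjusted p = 0.186). The type I interferon list was higher by camera (adjusted p = 0.00212; 0.651 with an estimated correlation), with 16 of 19 members above 0, 0 called and 3 higher adjusted over the list alone, among them Xaf1 (log2 0.85 ± 0.20, adjusted p = 0.137).

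In regulatory T-like cells, which suppress other T cells and carry the high-affinity IL-2 receptor, 0 of 5504 genes passed by edgeR, 367 had an unadjusted p below 0.05 and DESeq2 called 0. The IL-2 and STAT5 response list was higher by camera (adjusted p = 7.4e-05; adjusted p = 0.334 with an estimated correlation), with 19 of 23 members above 0 and 4 higher adjusted over the list alone. Socs1, a feedback inhibitor of cytokine signalling, was at 33.4, 71.3 and 85.4 CPM in PBS and 279, 295 and 88.6 CPM in treated libraries (log2 1.91 ± 0.42, adjusted p = 0.269). Cish, another such inhibitor, was at 199 ± 16.9 and 324 ± 18.9 CPM (log2 0.69 ± 0.19, adjusted p = 0.428) and the kinase gene Pim1 at 543 ± 12.4 and 805 ± 129 CPM (log2 0.57 ± 0.18). Gbp5, an interferon-induced GTPase gene of a family with similar sequences, was at 56.7 ± 15.6 and 157 ± 39.2 CPM (log2 1.47 ± 0.28, adjusted p = 0.263). Macrophage RNA differed in these cells too: 11 of 12 macrophage markers had negative values (camera adjusted p = 2.2e-05; 0.449 with an estimated correlation), with Apoe at log2 -0.99 and Lyz2 at -0.78. The MHC class II list, whose genes macrophages express, was lower as well (adjusted p = 0.000139; 0.449 with an estimated correlation; H2-Aa log2 -0.75), 3 of 7 members being lower adjusted over the list alone. Without PBS 1, 1 gene passed, and without TIM3-ProIL2V2 3, 57.

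In monocyte or macrophage-like cells the cell cycle lists were lower and the hypoxia and glycolysis lists higher by camera, though not with an estimated correlation, while 0 of 15433 single genes passed by edgeR (2035 at an unadjusted p below 0.05, 218 by DESeq2). Of the S phase list 36 of 37 members had negative values (camera adjusted p = 3.8e-12; 0.477 with an estimated correlation; 0 adjusted over the list alone), with the replication helicase gene Mcm2 at 22.6 ± 1.71 and 13.7 ± 3.97 CPM. Of the G2M phase list 50 of 52 did (camera adjusted p = 3.0e-08; 0.556 with an estimated correlation; 0 adjusted over the list alone). All 13 measured members of the hypoxia list were above 0 (camera adjusted p = 2.8e-08; 0.340 with an estimated correlation) and 8 were higher adjusted over the list alone, among them Ndrg1 (79.0 ± 11.2 and 142 ± 5.95 CPM) and the oxygen-sensing hydroxylase gene Egln3 (34.4 ± 1.92 and 67.4 ± 17.9 CPM). The glycolysis list was higher (camera adjusted p = 3.5e-08; 0.477 with an estimated correlation), with 12 members higher and 1 lower adjusted over the list alone and Gapdh at 3433 ± 302 and 4569 ± 316 CPM. Arg1, which encodes arginase 1, was at 1503 ± 176 and 2914 ± 188 CPM (log2 0.96 ± 0.12, adjusted p = 0.181), and Nos2, the inducible nitric oxide synthase gene, at log2 1.35 ± 0.33 (adjusted p = 0.347). This class joins 9 clusters whose mix differed between libraries: one with Arg1 among its leading genes held 6.51%, 6.24% and 3.60% of the class in PBS and 6.91%, 12.9% and 13.1% in treated libraries (exact permutation p = 0.1), one with Nos2 2.77%, 5.55% and 3.40% against 21.6%, 4.55% and 3.05% (exact permutation p = 0.6) and one led by cell cycle genes 11.9%, 14.2% and 17.03% against 4.59%, 11.4% and 13.8% (exact permutation p = 0.2). The mix was looked at after the data were seen, and changes within cells were not separated from it. The B cell marker list was lower (camera adjusted p = 0.00416; 0.477 with an estimated correlation; Cd79a 1.97 ± 1.99 and 0.111 ± 0.0337 CPM). Without TIM3-ProIL2V2 3, 287 genes passed.

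In dendritic-like cells the glycolysis and hypoxia lists were higher in treated tumours by camera, but not with an estimated correlation (adjusted p = 0.137 for both). Pgk1, a glycolytic kinase gene, was at 324, 336 and 325 CPM in PBS and 490.0, 512 and 497 CPM in treated libraries (log2 0.61 ± 0.09, adjusted p = 0.251), and Tpi1, another glycolytic enzyme gene, at 266, 299 and 295 against 445, 441 and 445 CPM (log2 0.63 ± 0.09, adjusted p = 0.251). Bnip3, a hypoxia-induced mitophagy gene, was at 48.5 ± 7.98 and 85.8 ± 1.31 CPM (SD, n = 3) and Ndrg1 at 85.1 ± 2.22 and 128 ± 4.22 CPM. All 16 members of the glycolysis list were above 0 (camera adjusted p = 3.1e-17; fry adjusted p = 0.0138) and 12 were higher adjusted over the list alone. Of the hypoxia list 11 of 12 were above 0 (camera adjusted p = 4.5e-12; fry adjusted p = 0.0327), and 10 were higher adjusted over the list alone. The S phase list was lower (camera adjusted p = 6.5e-12; 0.523 with an estimated correlation), with 34 of 36 members below 0, 0 adjusted over the list alone and Mcm5 at log2 -0.56. Over all genes edgeR called 0 of 10918 (995 at an unadjusted p below 0.05, 32 by DESeq2), and 209 without TIM3-ProIL2V2 3.

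**Figure D4:**
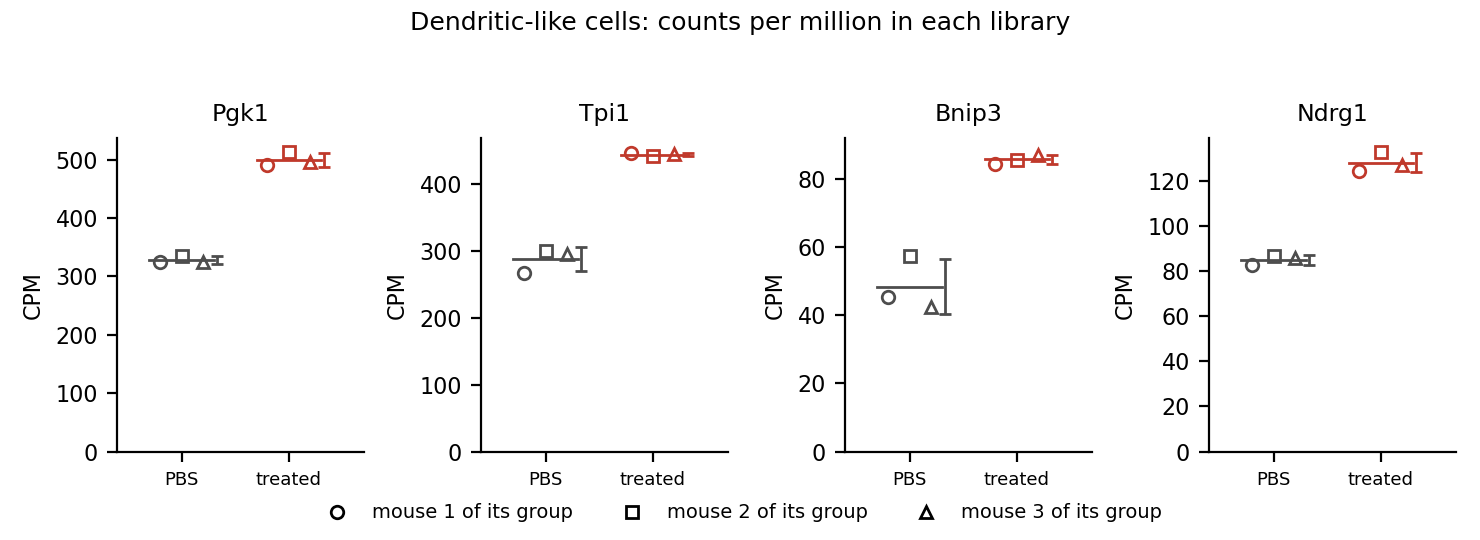
CPM, UMI counts scaled to library size (linear axes from 0) of 4 genes of the glycolysis and hypoxia lists in dendritic-like cells of each PBS and TIM3-ProIL2V2 (treated) library; open symbols are mice, horizontal lines are group means and error bars are 1 SD. For Tpi1 the PBS libraries lie at 266, 299 and 295 CPM and the treated ones at 445, 441 and 445 CPM.

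In neutrophil-like cells the hypoxia list was higher by camera (adjusted p = 9.2e-09; adjusted p = 0.176 with an estimated correlation), with 10 of 11 members above 0 and 3 higher adjusted over the list alone. Ndrg1 was at 58.4, 51.1 and 60.6 CPM in PBS and 93.0, 163 and 151 CPM in treated libraries (log2 1.25 ± 0.27, adjusted p = 0.754) and Egln3 at 151, 143 and 89.9 against 465, 239 and 245 CPM (log2 1.31 ± 0.32, adjusted p = 0.754). Single genes that passed by edgeR numbered 0 of 6656, with 384 at an unadjusted p below 0.05 and 0 by DESeq2. Without TIM3-ProIL2V2 3, 3 passed.

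The libraries also fell apart in a way that the groups do not explain. In each of 5 cell classes, 52 of 3758 genes were at least 0.5 log2 units higher in TIM3-ProIL2V2 1 and 2 than in each of the other 4 libraries. In monocyte or macrophage-like cells Taf10, a transcription factor subunit gene, was at 225 and 231 CPM in TIM3-ProIL2V2 1 and 2, at 21.0 CPM in TIM3-ProIL2V2 3, and at 23.9, 32.7 and 28.5 CPM in the PBS libraries. Hras, which encodes a signalling GTPase, was at 68.1, 77.4 and 12.4 CPM against 11.9, 12.5 and 13.7 CPM. Of the 21 genes called in CD8 T-like cells, 0 were among these 52, and no fixed list held any of them. The 52 were picked to be higher in TIM3-ProIL2V2 1 and 2 than in TIM3-ProIL2V2 3, with CD8 T-like cells among the 5 classes. Such genes vary within the treated group and can hardly pass with all 6 libraries. That 0 were called therefore does not show whether a library difference bears on the 21 calls. When TIM3-ProIL2V2 3 was left out, 52 of the 228 calls in CD8 T-like cells and 47 of the 287 in monocyte or macrophage-like cells were of these 52 genes, which follows from how they were picked. In NK-like and dendritic-like cells they were 51 of 293 and 50 of 209 calls. Regulatory T-like and neutrophil-like cells were not used to pick them, and there they were 28 of 57 and 3 of 3 calls. These genes were found after the data were seen.

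**Figure D5:**
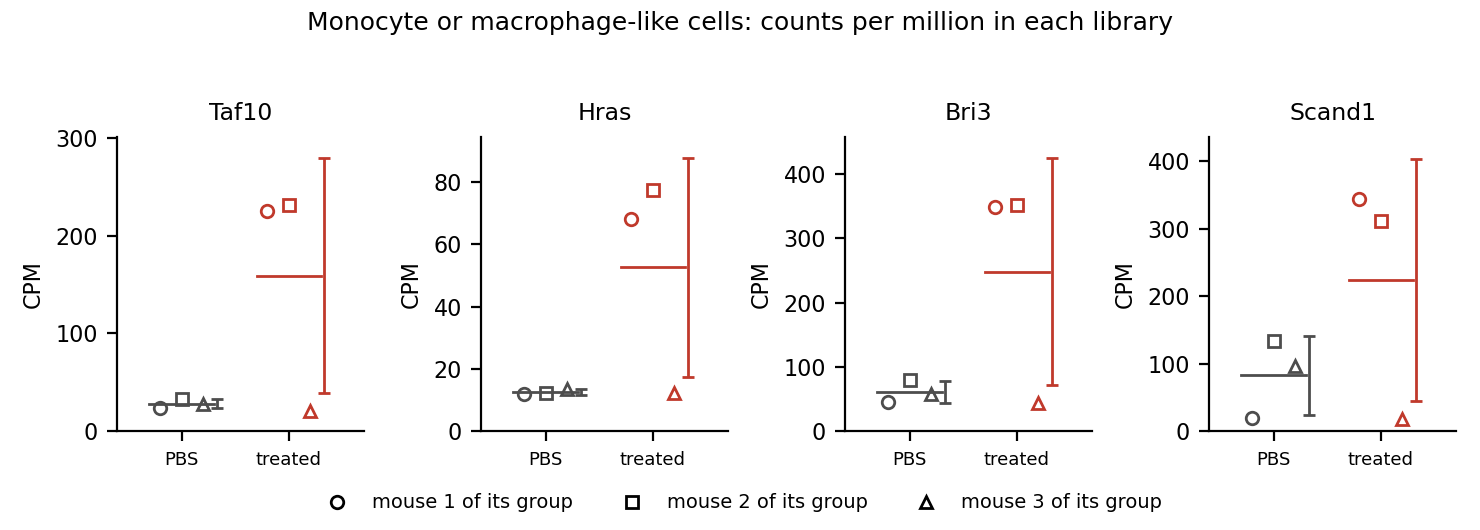
CPM, UMI counts scaled to library size (linear axes from 0) of 4 of the 52 genes in monocyte or macrophage-like cells of each PBS and TIM3-ProIL2V2 (treated) library; open symbols are mice, horizontal lines are group means and error bars are 1 SD. For Bri3 the libraries TIM3-ProIL2V2 1 and 2 lie at 349 and 351 CPM and TIM3-ProIL2V2 3 at 44.3 CPM, with the PBS libraries at 45.3, 80.4 and 58.0 CPM.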

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

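The tests of free macrophage RNA, of the difference of TIM3-ProIL2V2 1 and 2 from the other libraries, and of the called genes in low-Ptprc cells were chosen only after the result was seen.

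For 7 genes the treatment effect differed between CD8 T-like cells with and without a Havcr2 UMI by the interaction test of edgeR. The differences of log2 fold changes were -2.78 for Ccl3, 5.51 for Csf2, -2.18 for Ccl4, 2.63 for Gzma, 1.40 for Gzmf, -1.70 for Chn2 and -1.30 for Cx3cr1. That of Csf2 rested on 2 sums: cells without a Havcr2 UMI in PBS 1 had 205 CPM and those with one in TIM3-ProIL2V2 1 had 67.2 CPM, while all others lay between 3.00 and 21.7 CPM. Without PBS 1 or TIM3-ProIL2V2 1 Csf2 did not pass (adjusted p = 0.272 and 0.812; 2.4e-29 to 1.00 over its alternatives). Ccl3 passed whichever library was left out. Without PBS 1, Gzmf, Chn2 and Cx3cr1 did not pass (edgeR adjusted p = 0.225, 0.225 and 0.210). The Gzma difference turned to -0.59 in gated cells outside the mixed clusters, and DESeq2 called 2 genes, Ccl3 and Gzma. How far macrophage RNA bears on these differences was not tested.

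Barcodes that carried T or NK genes and macrophage genes held 10.0% ± 0.768 of kept cells in PBS and 4.12% ± 1.22 in treated tumours (SD, n = 3; exact permutation p = 0.1). Without doublet removal the shares were 11.5% ± 0.872 and 7.48% ± 3.67 (exact permutation p = 0.3), with 11.6% in TIM3-ProIL2V2 1, so that all treated libraries lay below all PBS libraries depends on that step. Free macrophage RNA in droplets with a single lymphocyte is argued against by their depth: the ratio of median UMIs in mixed barcodes to T and NK cells was 2.4531 at the lowest of the 6 libraries. Chance meetings of 2 cells in a droplet should give T and B cells like shares of barcodes with macrophage RNA. The libraries with over 100 B-like cells, PBS 1 and PBS 3, were set in advance for this test. The share was 71.6% of T and 44.9% of B cell barcodes in PBS 1 and 81.5% and 58.3% in PBS 3, ratios of 1.59 and 1.399 around the limit of 1.5. In PBS 2 and TIM3-ProIL2V2 1, 2 and 3, with 45 to 104 B cell barcodes, the ratios were 0.792, 0.473, 0.789 and 1.21. These ratios therefore cannot tell chance meetings from pairs of cells that stick together. The doublet removal assumed that 6.10% (PBS 2) to 10.2% (TIM3-ProIL2V2 2) of barcodes held 2 cells. T cell barcodes with macrophage RNA were above that in all 6 libraries, from 36.7% (TIM3-ProIL2V2 1) to 81.5% (PBS 3). The 2 measures are unlike: the assumed rate is a share of all barcodes, the other a share of T cell barcodes alone. Chance pairs make up a larger share of the barcodes of a scarce cell type, so the gap is smaller than it looks. The T cell shares still argue against chance meetings at the assumed rate as the whole source of these barcodes. That rate was not measured, so chance meetings at a higher rate stay open. A lower share of mixed barcodes in treated tumours after doublet removal may come from chance meetings, from pairs that stick together or from the removal. It may also come from fewer contacts of these cells in the tumour, for which no test was run.

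Genes lower in CD8 T-like cells of treated tumours, 12 by edgeR, had a median log2 fold change of -1.95. Less macrophage RNA among these cells as the whole cause is argued against by the macrophage list, whose median was -0.17045 with an SD of 0.469 over its members. The 12 genes were picked for being lower in the same data, which by itself widens that gap. A part that comes from less macrophage RNA stays open. Less RNA from dendritic cells, which express Ccr7 and Cxcl10, stays open: the median of their other markers was -0.0382, but only 3 of 11 (Socs2, Tmem123 and Cd63) were measured. T cells express these 3 as well, so the bound set in advance could not be used. In gated cells outside the mixed clusters, values were log2 -2.58 for Ccl1 in CD8 T-like cells and -2.57 for Ccr7 in CD8 T-like cells, both past the threshold, while Cxcl10 did not pass there, which is consistent with a part of the Cxcl10 change that depends on how the class was drawn; an effect of the treatment stays open for all 12 genes.

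Without TIM3-ProIL2V2 3 the calls rose from 21 to 228 in CD8 T-like and from 0 to 287 in monocyte or macrophage-like cells. A bias of that library along the GC content of whole transcripts is argued against, since a GC correction left 0 calls over all 6 libraries in monocyte or macrophage-like cells (306 without the library). These are 3' libraries, and a bias on the GC content of the sequenced fragments was not tested. The correction ended the 1 call in NK-like cells, Ccl5 (log2 1.04 ± 0.13 before and 1.04 ± 0.14 after, adjusted p = 0.0415 and 0.0537), by a slightly larger standard error, and in CD8 T-like cells that of Malat1 (log2 -0.60 ± 0.10 and -0.53 ± 0.099, adjusted p = 0.0372 and 0.0614), by a smaller change. Deviations of that library from the other treated ones were shared by cell classes, with a lowest correlation across genes of 0.65191 between monocyte or macrophage-like cells and 4 other classes (genes are not independent replicates). Of the PBS libraries, PBS 1 was above the bound of 0.3 as well (lowest 0.388), and PBS 2 and 3 were not (0.150 and 0.179). For TIM3-ProIL2V2 1 and 2 the lowest were 0.379 and 0.417. Each library was set against the mean of the other 2 of its group, so a shift of TIM3-ProIL2V2 3 enters these 2 values. They therefore cannot tell whether those 2 libraries have a shared shift of their own. The correlation of TIM3-ProIL2V2 3 was the highest of the 6 libraries in each of the 4 classes. TIM3-ProIL2V2 1 and 2 differed from the other 4 libraries in 52 genes in all 5 classes, against 17 for the next of the 15 splits into 2 and 4, a difference found in the same data. By the way they were picked these genes tend to be called in those classes once TIM3-ProIL2V2 3 is left out, and they were 52 of the 228 and 47 of the 287 calls. In regulatory T-like and neutrophil-like cells, not used to pick them, they were 28 of 57 and 3 of 3 calls. How far a difference of those 2 libraries accounts for the added calls stays open. Of the 13 CD8 calls with a mean of at least 5 CPM in low-Ptprc cells, 3 (Bach2, AA467197 and Malat1) lay apart the same way there (a share of 0.231). This leaves open for these 3 whether a library difference or the CD8 cells changed. The share lay between the bounds set for this test, which therefore cannot tell for the calls as a set. Gzmg, Ccl1, Ccr7, Gzmf and Gzmc were among the calls too low there to be checked (0.191, 0.358, 0.760, 3.32 and 4.91 CPM).

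The splits of the 6 libraries into 3 and 3 number 10, the real one included, so no share below 0.1 can be had. In CD8 T-like cells only the real split itself gave that many calls (21 against at most 3 in the others). The same held in Havcr2-detected cells (17 against 3), in NK-like cells (1 against 0), in the interaction (7 against 3) and for CD8 gene lists (15 against 13). In Havcr2-undetected cells 3 splits, the real one among them, gave at least as many calls as the real one (3 against up to 4). All 10 did in regulatory T-like (0 against 27), monocyte or macrophage-like (0 against 0), dendritic-like (0 against 0) and neutrophil-like cells (0 against 5) and for class shares (0 against 0). Any split reaches a real count of 0, so this was certain in advance. In regulatory T-like cells the split that calls 27 genes sets PBS 1, PBS 2 and TIM3-ProIL2V2 3 against PBS 3 and TIM3-ProIL2V2 1 and 2, which points to a structure of the samples other than their groups.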

How the results depend on the processing

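The gate outside mixed clusters, TIM3-ProIL2V2 3 alone against PBS, equal totals of the Havcr2 subsets for detected cells and the interaction, and 2 other ways to count class shares were tests chosen only after the result was seen. The alternatives for helper CD4 and B-like cells were not run, since neither class was tested. For the named genes, leaving out 1 library kept direction and side of the threshold 396 times, ended a call 91 times, made a call 24 times and turned the direction 5 times; the other settings did so 614, 44, 74 and 11 times. For the gene lists the numbers were 74, 2, 1 and 1, and 30, 30, 1 and 11. Many named genes and some lists were not called in the main analysis and so had no call to end. The numbers kept include those that stayed uncalled, and do not measure how stable the calls are. With RLE scaling or no Scrublet removal the gene counts stayed within 1.5 times those reported (28 and 21 in CD8 T-like cells), and a mitochondrial limit of 5%, run for CD8 T-like cells alone, gave 23. Over all settings the log2 fold change of Gzmg ran from 2.81 to 5.05, that of Ccl1 from -3.03 to -0.77 and that of Ccr7 from -3.47 to -0.77. Where a result did not hold, the cause was not tested.

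Leaving out each library in turn gave 7 to 228 genes in CD8 T-like cells, 0 to 186 in Havcr2-detected and 1 to 103 in Havcr2-undetected cells, 0 to 57 in regulatory T-like, 0 to 293 in NK-like, 0 to 287 in monocyte or macrophage-like, 0 to 209 in dendritic-like and 0 to 3 in neutrophil-like cells and 3 to 14 in the interaction. The highest of these was without TIM3-ProIL2V2 3 in every case. CD8 gene lists called by camera numbered 12 to 14, classes of cells 0 to 1 (B-like without PBS 2, dendritic-like without TIM3-ProIL2V2 1) and genes with a share of cells apart between the groups 5 to 8 (8 without PBS 2). Directions turned for Il2ra (log2 -0.17 without TIM3-ProIL2V2 1 to 0.24), Ifng (-0.39 to 0.49 without PBS 1), Mki67 (-0.13 without PBS 1 to 0.51, negative also without PBS 3 and TIM3-ProIL2V2 1) and the macrophage list in CD8 T-like cells (adjusted p = 0.159 without TIM3-ProIL2V2 1; range 0.00331 without TIM3-ProIL2V2 2 to 0.507).

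DESeq2 called 74 genes in CD8 T-like, 50 in Havcr2-detected, 22 in Havcr2-undetected, 26 in NK-like, 218 in monocyte or macrophage-like and 32 in dendritic-like cells and 2 in the interaction. Without a filter on low counts edgeR called 420, 297, 161, 90 (regulatory T-like), 337 (NK-like), 0 (monocyte or macrophage-like), 234 (dendritic-like), 120 (neutrophil-like) and 41 (interaction). On simulated data with no change this setting gave 0, 0, 1, 0, 2, 27, 9 and 1 calls in the same order. The interaction was not simulated without the filter. With the replicate number as a block, a pairing that the labels do not state and that correlations between same-numbered libraries (-0.14, -0.051 and -0.025 in CD8 T-like cells) do not show, the counts were 32 in CD8 T-like, 49 in Havcr2-detected, 6 in Havcr2-undetected, 2 in regulatory T-like, 0 in NK-like and 19 in neutrophil-like cells, and Ifng was at log2 0.017. Etv6 (adjusted p = 0.0562) and Malat1 (0.114) in CD8 T-like, Ccr7 in Havcr2-undetected (0.0837) and Ccl5 in NK-like cells (0.118) did not pass with that block.

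With CD8 cells taken by the gate on UMIs, mixed barcodes included, 1604 genes passed. There the direction turned for Il2rg (log2 0.27), Ifng (0.89), Cd8a (0.92), Ccl4 (0.17) and Klra4 (0.46), and for the lists of cytokines (adjusted p = 0.943), glycolysis (0.988), hypoxia (0.468), IL-2 and STAT5 response (0.0195), exhaustion (0.00818), KLRG1-type effectors (0.264), costimulatory receptors (0.00434) and NK markers (0.0929), and the stem-like list did not pass (0.988). Gated cells outside the mixed clusters gave 15 genes, 20 in Havcr2-detected, 5 in Havcr2-undetected cells and 10 in the interaction. Directions turned there for Ifit3 (log2 0.10), for Gzma in the interaction (-0.59) and for the lists of type I interferon (adjusted p = 0.904), IL-2 and STAT5 response (0.921) and macrophage markers (0.921), while the cytotoxic, stem-like, cytokine, oxidative phosphorylation, glycolysis, hypoxia and costimulatory lists passed. The KLRG1-type effector (adjusted p = 0.118), NK marker (0.284) and interferon-gamma response (0.499) lists no longer did.

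Sums thinned to the smallest library gave 33 genes in CD8 T-like cells with Mki67 at log2 -0.023, and cells with no Mki67 or Top2a UMI gave 53 with Il2ra at -0.49. Kdm2b did not pass in the thinned sums (adjusted p = 0.0735). Cells with at least 2 Havcr2 UMIs gave 6 genes, and Gzmf, Mt2, Chn2, Ccl4, Cx3cr1 and Zeb2 were not among them (0.0623 to 0.161). Equal totals of the Havcr2 subsets gave 20 genes in detected cells, 1 in undetected cells and 11 in the interaction, without Cx3cr1 (0.0525) in detected and Ccl3 or Ccr7 (0.0507 for both) in undetected cells. Zeb2 was at 0.0501 without Scrublet removal. TIM3-ProIL2V2 3 alone, assumed to vary like the PBS libraries, gave 49 genes in CD8 T-like, 71 in Havcr2-detected, 38 in Havcr2-undetected, 25 in regulatory T-like, 5 in NK-like and 1 in neutrophil-like cells, with Il2ra at log2 -0.31. With an estimated correlation camera called 0 lists in CD8 T-like cells (15 as reported) and 0 in other classes and subsets (61), and fry called 0 in CD8 T-like cells.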

Other observations

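The counts of genes that set libraries apart were made only after the result was seen.

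Lists of interferon genes were called in several classes with the preset correlation and in none with an estimated one. The interferon-gamma response list was higher by camera in monocyte or macrophage-like cells (adjusted p = 1.4e-06; 0.477 with an estimated correlation), in neutrophil-like cells (adjusted p = 1.1e-05; 0.568 with an estimated correlation) and in regulatory T-like cells (adjusted p = 0.00428; 0.449 with an estimated correlation), and lower in CD8 T-like cells (adjusted p = 0.0237; 0.517 with an estimated correlation and 0.499 in gated cells outside the mixed clusters). The type I interferon list was higher in neutrophil-like cells, with 24 of 25 members above 0 (adjusted p = 2.4e-10; 0.523 with an estimated correlation). In neutrophil-like cells Gbp4, an interferon-induced GTPase gene of a family with similar sequences, was at 29.4 ± 8.38 CPM in PBS and 60.7 ± 18.1 CPM in treated libraries (SD, n = 3; log2 1.09 ± 0.32, adjusted p = 0.760 by edgeR). Whether these effects differ between classes was not tested.

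The MHC class I list was higher by camera in dendritic-like cells (adjusted p = 4.2e-06; 0.530 with an estimated correlation) and in monocyte or macrophage-like cells (adjusted p = 1.2e-07; 0.477 with an estimated correlation), with 15 of 16 members above 0 in both. The S phase list was lower in neutrophil-like cells too (adjusted p = 1.9e-06; 0.510 with an estimated correlation), with 0 of 15 members above 0 and Mcm5 at log2 -1.80 ± 0.50 (adjusted p = 0.760). Markers of CD4 and regulatory T cells were lower in monocyte or macrophage-like cells (camera adjusted p = 0.00274; fry adjusted p = 0.0109; 0.340 with an estimated correlation), with 0 of 5 above 0 and 2 lower adjusted over the list alone.

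A split that sets PBS 1 and TIM3-ProIL2V2 3 apart from the other 4 libraries had 17 genes at least 0.5 log2 units lower in all 5 classes. In monocyte or macrophage-like cells Scand1, 1 of the 52 genes higher in TIM3-ProIL2V2 1 and 2, was at 19.3 and 18.2 CPM in PBS 1 and TIM3-ProIL2V2 3, at 133 and 97.1 CPM in PBS 2 and 3 and at 344 and 311 CPM in TIM3-ProIL2V2 1 and 2. Cells with little Ptprc RNA, the gene of CD45, held 8.31%, 6.0% and 8.39% of the PBS and 4.27%, 11.3% and 10.9% of the treated libraries, although the labels give CD45+ cells. Neutrophil-like cells held 0.940%, 1.25% and 0.544% against 7.45%, 0.810% and 1.04%.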
